A study of Nannochloropsis oceanica with 6 samples.

How the data were processed

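The series compared the transcriptome of wild-type (WT) Nannochloropsis oceanica IMET1, a unicellular marine alga, with that of 2 NoPAC4 knockout lines under low light. Polyadenylated RNA was sequenced from 6 libraries, 2 from WT and 2 from each line. Per the labels, cells grew for 5 days in continuous light of 50 µmol photons per square metre per second at 23 °C, while the growth text gives 25 °C for the cultures. RNA input was 2 µg per sample, and the kit named in the labels does not mark strand. Groups and replicate numbers came from the sample titles. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries.

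The authors deposited a gene table of expected counts, in which 20.1% of values were not whole (tolerance 1e-06). They also deposited a table of TPM for the same genes and libraries, whose columns sum to 1e+06. Per the submitters' processing notes, STAR and edgeR were used, with no version given. The counting program, the genome build and the annotation version were not given in the sources used here. Estimated counts split reads among genes with near-identical sequence, so values of gene copies are uncertain.

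The table held 10493 gene IDs. Of these, 10333 were nuclear IDs under 30 prefixes (NO01 to NO30), and 125 plastid and 35 mitochondrial IDs carried gene symbols. All 160 organelle symbols matched the reference gene table used here, and 0 nuclear IDs did. The files therefore do not pair nuclear IDs with names, and NoPAC4 itself was not analysed here. No source states that the order of IDs within a prefix is their order along a chromosome.

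Expected counts were rounded to whole numbers. The main test was edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3 with TMM factors and the default group filter on low counts, which left 9712 genes and removed 781. One model held all 3 groups, with 3 residual degrees of freedom and no replicate block. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. In 4 comparisons, the mean of both lines was set against WT, each line against WT, and line 1 against line 2. Standard errors come from the fitted test statistic. CPM are counts scaled to 1e+06 per library after the TMM factors. Where WT had 0 reads, folds are lower bounds against 3 reads over both WT libraries (0.0946 CPM for the group). These floors cover counting error only, not differences between cultures.

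Genes sharing an ID prefix were tested as 32 sets (30 nuclear, plastid, mitochondrial) with camera of limma 3.58.1 at a preset correlation of 0.01. In addition, 40 keyword lists for photosynthesis, lipid, nitrogen, protein and cell cycle functions were fixed before the data were examined. Only 4 lists met any gene symbol, and 0 had the 5 tested members needed for a test. Photosystem II had 4 tested members, photosystem I had 2, chaperones had 1 and photosynthetic electron transport had 0, and edgeR quasi-likelihood and limma-voom called 0 of these 7 members, DESeq2 called 1 (dnaK) and the edgeR likelihood ratio test called 2 (psbC and dnaK), with 2 at an unadjusted p below 0.05 in the first. Reads were also summed over 17 families, 16 of organelle genes and 1 run of nuclear IDs, and over the first and last 10 tested IDs of each nuclear prefix (60 ends). The ends and their size were chosen after a scan of 15 neighbouring IDs at a time. These sums entered the same edgeR model as added rows with their own Benjamini-Hochberg adjustment, and they were chosen after the data were seen.

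The text names, by rule, the 2 largest rises and 2 largest falls among nuclear genes called for both lines together and for each line alone in 1 direction, with all knockout libraries beyond both WT libraries and a mean of at least 5 CPM. As 0 falls met the rule, the 2 largest called falls are named, a choice made after their values were seen. Organelle genes are named as examples of their families, also after their values were seen.

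The code was tested on simulated data. On counts drawn with the real means and depths and with dispersions pooled over the groups (9712 genes, 5 draws), the quasi-likelihood test for both lines against WT recovered on average 91.0 of 100 genes changed 2-fold and 99.4 of 100 changed 4-fold, with 14.0 false calls. DESeq2 1.42.0 recovered 95.0 and 99.6, with 33.4 false calls. Pooled dispersions understate the spread of the WT libraries, so these rates may not hold for the real data. For a set of 25 genes, camera had an unadjusted p below 0.05 in 5 of 5 draws with a shift of -0.6 and in 1 of 5 draws without one. Because both lines share the WT libraries, 40 simulations of unchanged lines gave the values that shared controls alone produce. A first set used pooled dispersions, and a second, added after the data were seen, used a dispersion for each group. Alternatives were other scaling factors, DESeq2, limma-voom, the edgeR likelihood ratio test, other filters, thresholds and groupings, deposited TPM values with limma, replicate blocks, and each library left out in turn.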

Results

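Polyadenylated transcripts were counted in 6 libraries of Nannochloropsis oceanica IMET1 grown under low light, 2 from each of 2 NoPAC4 knockout lines and 2 from WT. The WT libraries lay farther apart than those of either line. Across 7099 genes above 20 CPM, the log2 ratio of the replicates had an SD of 0.45 in WT, 0.16 in line 1 and 0.22 in line 2, and 293, 14 and 9 genes differed more than 2-fold. The first principal component (48.7% of the variance) separated WT replicate 2 from the other libraries.

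The first comparison asked which transcripts differ between NoPAC4 knockout cells and WT in low light. A run of nuclear genes at the end of the IDs with prefix NO06 was transcribed in both knockout lines and had 0 reads in both WT libraries. The run held 18 IDs, and 11 of 17 IDs had reads in the knockout libraries alone, while 1 ID, at position 14 of the run, had 19 to 40 reads in every library. Summed over the 17 IDs, the reads were 1498 and 1498 in line 1, 403 and 451 in line 2, and 0 and 0 in WT. NO06G04580, the first ID of the run, reached 34.8 ± 20.8 CPM in the knockout libraries (SD, n = 4), at least 368-fold above the WT floor (edgeR adjusted p = 0.00142). NO06G04750, the last, reached 13.2 ± 7.80 CPM (SD, n = 4), at least 139-fold above that floor (edgeR adjusted p = 0.00448). These bounds are for the mean of both lines. For line 1 and line 2 alone they were 557 and 179-fold for NO06G04580 and 210 and 68.4-fold for NO06G04750.

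**Figure D1:**
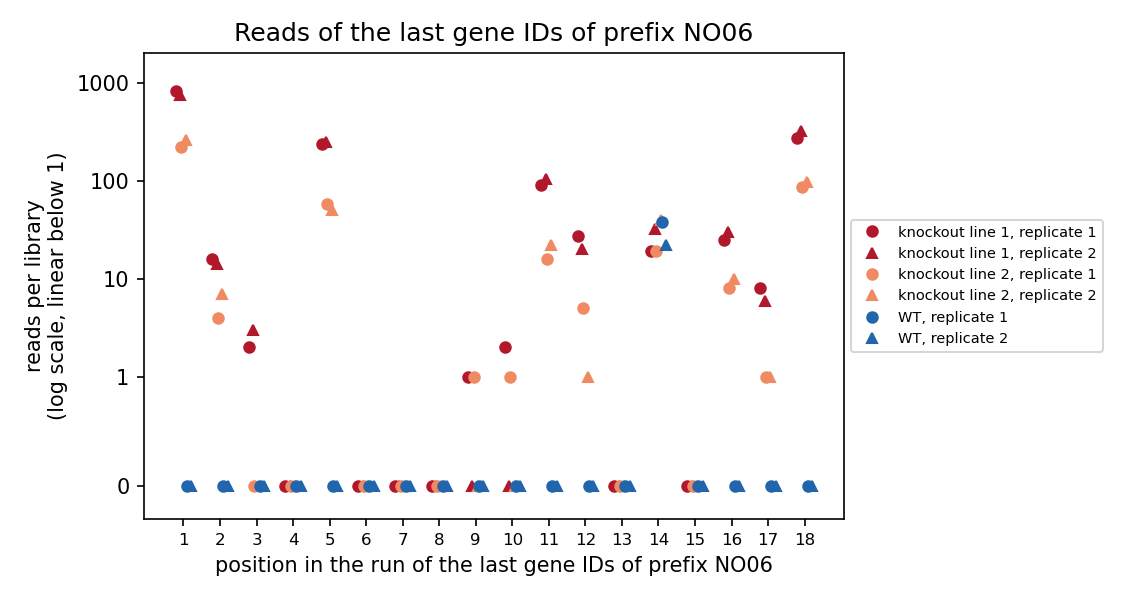
Reads per library (vertical axis, log scale that is linear below 1) of the 18 gene IDs at the end of prefix NO06, in the order of their IDs (horizontal axis, position in the run); colours mark the groups and symbols the replicates. Both WT libraries lie at 0 reads at every position except 14, where all 6 libraries hold reads.

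In all, 16 genes were called in the knockout lines against WT, 8 higher and 8 lower. Of the 8 higher genes, 4 lay in the NO06 run and 4 elsewhere, the latter with log2 fold changes from 1.48 to 4.43. The largest rise outside the run was from 1.29 ± 0.07 CPM in WT (SD, n = 2) to 28.5 ± 6.17 CPM (SD, n = 4), a log2 change of 4.43 ± 0.16 (SE, edgeR adjusted p = 0.000544). The 8 lower genes had log2 fold changes from -2.34 to -0.86. NO27G01660 fell from 26.4 ± 4.08 CPM in WT (SD, n = 2) to 5.43 ± 2.07 CPM (SD, n = 4), a log2 change of -2.34 ± 0.24 (SE, edgeR adjusted p = 0.0380). NO30G01280 fell from 8.96 ± 0.01 CPM (SD, n = 2) to 3.34 ± 0.39 CPM (SD, n = 4), a log2 change of -1.43 ± 0.16 (SE, edgeR adjusted p = 0.0475). One of the 50 most abundant transcripts was among the falls, at 4069 ± 310.0 CPM in WT (SD, n = 2) and 1776 ± 176 CPM in the knockout libraries (SD, n = 4), a log2 change of -1.20 ± 0.12 (SE, edgeR adjusted p = 0.0303). With upper-quartile factors the calls were 8 higher and 4 lower, without NO30G01280 (edgeR adjusted p = 0.0581). With log2(TPM + 1) or log2(TPM + 0.1) and limma they were 9 higher and 2 lower, 8 of them among the 16, and 3 of the named genes were not called. Of these, NO27G01660 stayed at -2.26 and -2.30 (limma adjusted p = 0.0713 and 0.0752) and NO30G01280 at -1.04 and -1.35 (limma adjusted p = 0.0771 and 0.0764), while the value of NO06G04750, with 0 reads in WT, depends on the constant added (limma adjusted p = 0.155 and 0.0803).

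The scaling factors hold the median log2 change of all tested genes near 0 (0.01), so a shift of all transcripts together is outside this test. At an unadjusted p below 0.05, 459 genes were higher and 941 lower, where 486 of 9712 were expected by chance in both directions together. That expected number assumes an equal spread in all groups, while the replicates differed more in WT (SD 0.45) than in the lines (0.16 and 0.22). An error pooled over the groups understates the WT spread, so the excess cannot be read as a number of changed genes. DESeq2 called 557 genes (94 higher, 463 lower), limma-voom 18 (10 higher, 8 lower) and the edgeR likelihood ratio test 674 (118 higher, 556 lower), and the first 2 of these lists held all 16 genes above. The number of calls depended on single libraries, with 2 calls without any 1 of the 4 knockout libraries, 2848 (1265 higher, 1583 lower) without WT replicate 1 and 511 without WT replicate 2. NO06G04580 was called in each of these 6 fits, whereas NO06G04750 and both named falls were called in none of the 4 fits without a knockout library (edgeR adjusted p from 0.0537 to 0.280).

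Most of the tested plastid genes had lower values in the knockout lines. The plastid share of all reads was 0.00933 and 0.0161% in line 1, 0.01146 and 0.01144% in line 2, and 0.01186 and 0.01150% in WT. Only line 1 replicate 2, which held 1227 psbA reads, lay above WT, and the other knockout libraries lay below both WT libraries. Reads of all plastid genes without psbA summed to a log2 change of -0.32 ± 0.11 that did not pass (SE, edgeR adjusted p = 0.0684 over 17 families). Of 25 plastid genes tested, 18 had log2 fold changes below 0 and 7 above, with a median of -0.59. As a set they were lower than other genes (camera adjusted p = 0.00758 over 32 prefix sets). The call was lost when camera estimated the correlation (camera unadjusted p = 0.0295, adjusted p = 0.945). That estimate, 0.00379, lay below the preset 0.01, so a stronger correlation among the genes was not the reason. The 30 nuclear prefixes had medians from -0.06 to 0.06 and a smallest camera adjusted p of 0.581. By gene, 0 of the 25 were called by edgeR quasi-likelihood or limma-voom, 0 were called when adjusted over the list alone, 4 had an unadjusted p below 0.05, DESeq2 called 1 and the edgeR likelihood ratio test 4. Plastid reads were few, 1380 to 2430 per library of polyadenylated RNA. The set was not called without WT replicate 1 (median -0.46, camera adjusted p = 0.315) or without WT replicate 2 (median -0.55, camera adjusted p = 0.215).

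**Figure D2:**
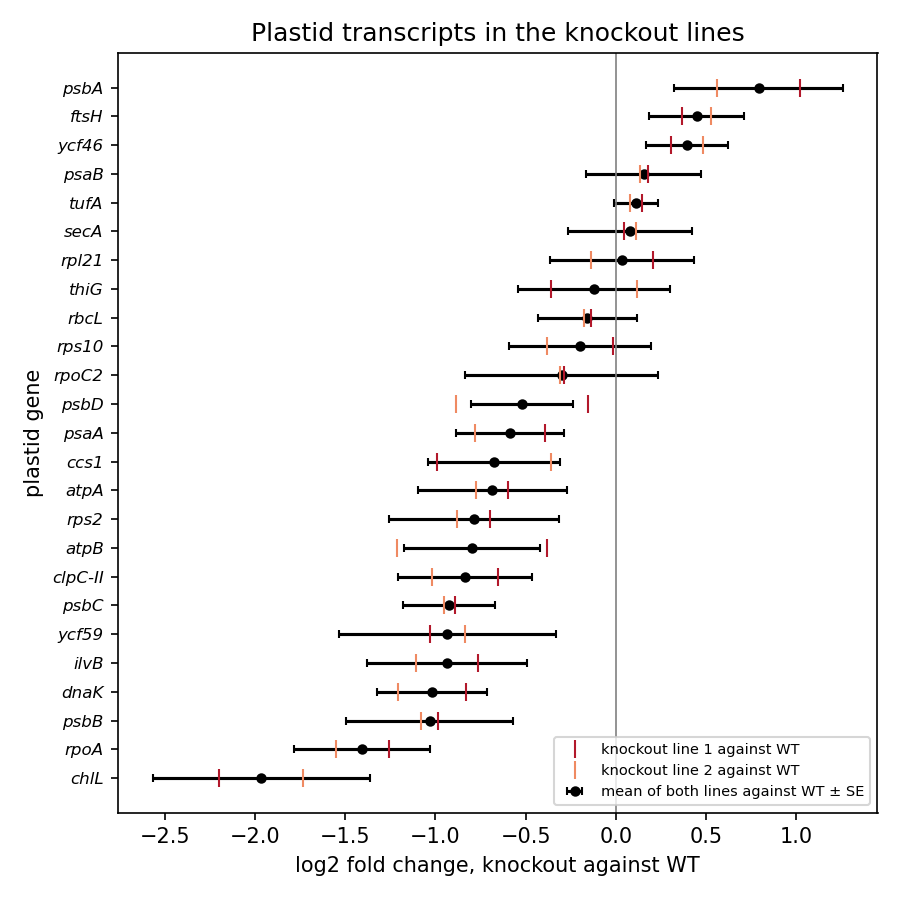
Log2 fold change of the 25 tested plastid genes in the knockout lines against WT (horizontal axis, black points with SE bars; coloured ticks for each line alone), one gene per line of the vertical axis. The 18 genes below 0 include psbC at -0.92 and rpoA at -1.41, and psbA lies at 0.79.

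Photosystem II genes other than psbA, which encode the core antenna and reaction centre proteins and small subunits, were lower when their reads were summed. This family was set apart from psbA after the data were seen. Only 3 of its 18 genes, psbB, psbC and psbD, passed the filter on low counts. They held nearly all of its reads, with 16 and 24, 74 and 89, and 58 and 37 of 151 and 152 in WT. The sum therefore says little about the small subunits. By line, the 18 genes together passed in line 2 (-0.93 ± 0.21, SE, edgeR adjusted p = 0.0297) but not in line 1 (-0.60 ± 0.21, SE, edgeR adjusted p = 0.137). Over both lines they had 5.67 ± 0.97 CPM in the knockout libraries (SD, n = 4) and 9.57 ± 0.51 CPM in WT (SD, n = 2). This was a log2 change of -0.77 ± 0.18 (SE, edgeR adjusted p = 0.0322 over 17 families), with all 4 knockout libraries below both WT libraries. This call was lost without line 1 replicate 1 or line 1 replicate 2 (edgeR adjusted p = 0.0816 and 0.0994). Within the family, psbC, for the CP43 antenna protein, had a log2 change of -0.92 ± 0.26 (SE, edgeR adjusted p = 0.143), which passed without WT replicate 1 (-1.10, edgeR adjusted p = 0.0290). The log2 changes of psbB, for CP47, and psbD, for the D2 protein, were -1.03 and -0.52, with psbB at -0.68 without WT replicate 2 and psbD at -0.22 without WT replicate 1 and -0.79 without WT replicate 2. By contrast, psbA, for the D1 protein, stood at 0.79 ± 0.47 (SE, edgeR adjusted p = 0.530), with 1227 reads in line 1 replicate 2, 330 to 604 in the other libraries and a change of 0.18 without the former. It held most photosystem II reads, and all 19 photosystem II genes summed to 50.3 ± 25.7 CPM in the knockout libraries (SD, n = 4) and 35.1 ± 0.23 CPM in WT (SD, n = 2), a log2 change of 0.50 ± 0.41 (SE). Photosystem I genes summed to a log2 change of -0.17 ± 0.21 (SE), with psaA at -0.59 and psaB at 0.15 (-0.16 without line 1 replicate 2, 0.36 without line 1 replicate 1, 0.02 and 0.28 without WT replicate 1 and 2), and the 2 Rubisco genes to -0.15 ± 0.27 (SE).

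No other plastid family passed the test. The 4 plastid RNA polymerase genes summed to 1.61 ± 0.40 CPM (SD, n = 4) against 3.38 ± 0.30 CPM in WT (SD, n = 2). This was a log2 change of -1.07 ± 0.30 (SE, edgeR adjusted p = 0.0546 over the families). Of the 2 genes tested singly, rpoA stood at -1.41 ± 0.38 (SE) and rpoC2 at -0.30 ± 0.53 (SE), the latter with knockout and WT libraries overlapping. Chaperone and protease genes summed to -0.76 ± 0.22 (SE, edgeR adjusted p = 0.0546), -0.48 without WT replicate 1 and -1.02 without WT replicate 2 (edgeR adjusted p = 0.201 and 0.00582). Without line 2 replicate 2 both sums passed (edgeR adjusted p = 0.0450). Among them dnaK, for the plastid Hsp70 chaperone, was at -1.02 ± 0.30 (SE), -0.61 without WT replicate 1 and -1.36 without WT replicate 2 (edgeR adjusted p = 0.148 and 0.0225), and ftsH, for a membrane protease, at 0.45. ATP synthase genes summed to -0.54 ± 0.23 (SE), and chlL, for a subunit of the light-independent protochlorophyllide reductase, was at -1.97 ± 0.60 (SE, edgeR adjusted p = 0.186), while the 3 genes of that enzyme summed to -0.43 ± 0.53 (SE), with knockout and WT libraries overlapping. The elongation factor gene tufA, at 19.0 and 17.6 CPM in knockout and WT libraries, had a log2 change of 0.11 ± 0.12 (SE), 0.06 and 0.07 without replicate 2 of line 1 and of line 2.

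Mitochondrial genes showed no common shift. The 10 tested genes had a median log2 change of 0.18 (camera adjusted p = 0.970), and all 35 together summed to -0.01 ± 0.15 (SE). By gene, 0 were called by edgeR quasi-likelihood, DESeq2 or limma-voom, 2 had an unadjusted p below 0.05 in the first, and the edgeR likelihood ratio test called 1. The values of nad7, for a complex I subunit, cox1, for a cytochrome oxidase subunit, and atp1 were -1.34 ± 0.38, 0.48 ± 0.26 and -0.73 ± 0.29 (SE), with cox1 at 0.31 without line 1 replicate 2. Mitochondrial reads numbered 170 to 227 per library.

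The next comparisons asked what each knockout line shows on its own. In line 1, 13 genes were called, 10 higher, of which 4 lay in the NO06 run, and 3 lower, of which 2 lay among the first 10 tested IDs of NO18. In line 2, 4 genes were called, all higher, of which 3 lay in that run; 0 genes were called lower by edgeR quasi-likelihood or limma-voom, while 841 were lower at an unadjusted p below 0.05 and DESeq2 called 338 lower and the edgeR likelihood ratio test 381. The fourth call in line 2 was the gene with the largest rise outside the run, at 33.7 CPM in line 1 and 23.2 CPM in line 2 against 1.29 CPM in WT. Without WT replicate 1 the calls were 3153 in line 1 and 1549 in line 2, and without WT replicate 2 they were 214 and 665. Without 1 of the 4 knockout libraries, 2 to 5 genes were called in line 1 and 1 to 2 in line 2.

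All 4 genes called in line 2 were also called in line 1, in the same direction, 3 of them in the NO06 run. Simulated unchanged lines against the same WT libraries, drawn with the spread of each group, shared 0 to 1 calls in 40 draws, and independent lists of these sizes would share 0.00412 higher genes. Across genes, which are not independent replicates, the log2 fold changes of the lines correlated at 0.731, and at 0.633 without the run. This was not above the correlation from shared WT libraries alone, 0.777 (0.762 to 0.793) in these simulations, while simulations with dispersions pooled over the groups, which understate the WT spread, gave 0.498 (0.440 to 0.562). The covariance was 0.152, and 0.0961 without the run, against 0.0597 simulated with the spread of each group and 0.0367 with pooled dispersions. With a separate WT library for each line the correlation was 0.375 or 0.0620, depending on which library went with which line, and part of any excess may come from the shared WT libraries.

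The last comparison asked whether the knockout lines differ from each other. By single genes, 0 were called by edgeR quasi-likelihood or limma-voom, with 364 at an unadjusted p below 0.05 in the former where 486 were expected. The error was pooled over all groups, including the more variable WT, so this shortfall does not show that the lines are alike. With only the lines in the fit, 12 genes were called. DESeq2 called 17 (10 higher, 7 lower in line 1) and the edgeR likelihood ratio test 23. Leaving out either WT library gave 12 calls. Summed over the NO06 run, line 1 had 100.3 ± 2.48 CPM and line 2 had 29.9 ± 2.38 CPM (SD, n = 2 each), 3.36-fold more in line 1, a log2 difference of 1.75 ± 0.13 (SE, edgeR adjusted p = 0.000311 over 17 families).

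At 3 other prefix ends, line 1 lay below both line 2 and WT. This was seen in the sums over the first and last 10 tested IDs of the 30 prefixes. The first 10 IDs of NO30 had 124 and 102 reads in line 1, 330 and 333 in line 2, and 358 and 395 in WT, a log2 difference between the lines of -1.61 ± 0.18 (SE, edgeR adjusted p = 0.00180 over 60 ends). The first 10 IDs of NO18 had 1293 and 1118 reads in line 1, 2534 and 3047 in line 2, and 4432 and 4938 in WT. Most were reads of 2 neighbouring genes, with 522 and 465, and 500 and 395, in line 1, and 2048 and 2175, and 1782 and 2115, in WT. A gene just past these 10 IDs went the other way, at 2.83 in line 1 against WT (edgeR adjusted p = 0.0236). Between the lines, 9 of the 10 genes were lower in line 1, with a median of -1.38. The sum had a difference of -1.27 ± 0.17 (SE, edgeR adjusted p = 0.00358). This call was lost without line 1 replicate 2 (edgeR adjusted p = 0.0702), and 3.76% of the reads were in genes with whole counts. The last 10 IDs of NO09 had 172 and 108 reads in line 1, 278 and 346 in line 2, and 412 and 526 in WT, a difference of -1.21 ± 0.28 that did not pass (SE, edgeR adjusted p = 0.0679), though it passed without line 1 replicate 1 or either WT library (edgeR adjusted p = 0.0382, 0.00455 and 0.00483). In the other 56 ends the median difference between the lines lay between -0.22 and 0.18. Some of these were lower in both lines together against WT, with differences of 0.02 to 0.11 between the lines. The ends of NO17, NO11, NO15 and NO01 and the start of NO05 summed to -1.01, -0.62, -0.50, -0.52 and -0.55 (edgeR adjusted p from 0.000886 to 0.0287). At NO17 and NO01 the median gene was at 0.00 and -0.03. Most reads at the end of NO17 came from 1 gene, with 63107 and 65639 of 81744 and 82196 in WT. It is the abundant transcript already given among the falls, so that sum is not a separate result. Genes at the ends of NO30 and NO09 were weakly transcribed, with a median of 0.892 and 0.972 CPM against 45.6 CPM for all tested genes.

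**Figure D3:**
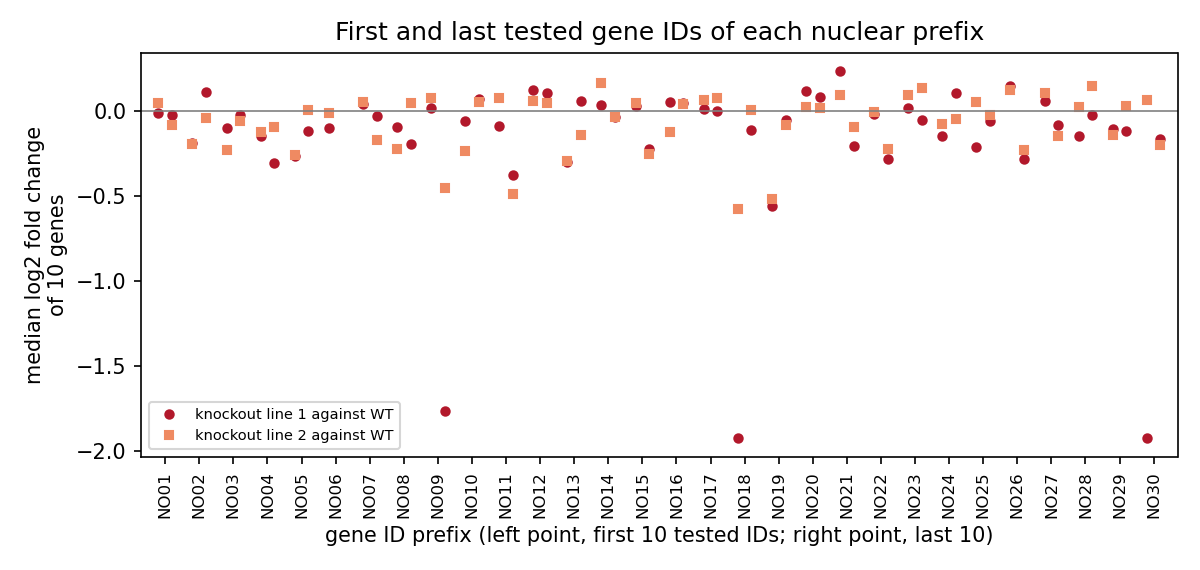
Median log2 fold change against WT (vertical axis) of the first 10 and the last 10 tested gene IDs of each of the 30 nuclear prefixes (horizontal axis), for knockout line 1 (circles) and line 2 (squares); the end of NO06 is left out because genes there have 0 WT reads. The start of NO30, the start of NO18 and the end of NO09 lie at -1.93, -1.92 and -1.77 in line 1 and at 0.06, -0.58 and -0.45 in line 2.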

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

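The tests of explanations in this part, and the sums over runs of gene IDs, were chosen only after the results were seen, the ends after a scan in which 15 IDs of NO30 had a median of -1.36 between the lines (largest of 100 shuffled orders 0.35 in size).

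The knockout lines differed in the transcripts of the NO06 run, with a log2 difference of 1.75 between line 1 and line 2, while WT had none. Depth argues against chance zeros, since 947 reads would be expected in WT at the level of line 2, and reads passed between near-identical genes are disfavoured, as 84.6% of the reads lay in the 9 of 11 genes whose counts were whole in every library. A mixture of line 1-like and WT-like cells in line 2 was first tested with counting error only, which argued against it (permutation p = 0.00811), and after that result the error was taken from the fit, with which the 7 tested genes were alike (heterogeneity Q of 9.25 against a 5% limit of 12.6), so the answer depends on the error used. Such a mixture alone would put line 2 at 29.8% of the way from WT to line 1. Of the 9 genes called in line 1 outside the run, 4 had 95% intervals wholly above that point, at positions of 0.548 to 0.815 against 0.298. A mixture as the only difference is disfavoured for these 4 genes, while the intervals of the others included that point. For the run itself, a mixture cannot be told apart from a difference in transcription. A WT culture that lacks every ID of the run is disfavoured by 60 WT reads, with whole counts, at position 14, but loss of the other IDs alone was not tested, and it remains open whether the difference arose with the knockout or with the history of the cultures.

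Line 1 was also lower than line 2 at the start of NO30 and at the start of NO18, with log2 differences of -1.61 and -1.27. The end of NO09 did not pass, and its difference was -0.91 without line 1 replicate 2 and -1.62 without line 1 replicate 1 (edgeR adjusted p = 0.379 and 0.0382). The differences, of which that of NO09 was nearest to 0 at -1.21, use no WT reads but draw their errors from all groups, and with only the lines in the fit NO30 and NO18 passed (edgeR adjusted p = 5.98e-05 for each), so WT spread is disfavoured there. Reads divided among gene copies are disfavoured for NO30 and NO09, where at least 82.6% of reads lay in genes with whole counts, but cannot be told apart from a change in transcription at NO18, where 3.76% did. Absence of all 10 IDs from every line 1 cell is disfavoured at NO30 and NO09. At least 192 summed line 1 reads at each lay in genes with whole counts, though whole counts alone do not show the origin of reads. The sum cannot exclude loss of only some of the 10 IDs from all line 1 cells, which was not tested. Loss from part of the line 1 cells would lower all genes of an end alike. Heterogeneity Q was 10.6 at NO30, 38.7 at NO18 and 18.0 at NO09 against a limit of 16.9. No verdict was drawn from it, because 10 IDs may reach past the lost part. Both kinds of loss stay open beside a change in transcription.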

How the results depend on the processing

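The edgeR likelihood ratio test, the simulations with the spread of each group, the fit without both libraries that carry number 3 in their descriptions, and the sums over families and prefix ends were chosen only after the data were seen; the other alternatives were set before.

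Scaling by other factors moved the median of all genes by at most 0.01 (log2), and RLE factors gave the same counts of calls. Other tools, filters and groupings moved the counts, in most cases upward; unless stated, the cause was not tested. Both lines together, 16 genes in the report, gave 557 with DESeq2, 674 with the likelihood ratio test, 233 without a filter, 216 with a filter of 5 CPM, 318 as 1 knockout group (14 of the 16 among them), 4 at an adjusted p below 0.01 and 1417 without the number 3 libraries. Line 1 against WT, 13 genes, gave 403, 485, 5 with only its own groups in the fit, 7 at 0.01 and 1027 without the number 3 libraries. Line 2 against WT, 4 genes, gave 374, 436, 1, 2 and 1353 in that order, and 9 with log2(TPM + 0.1) and limma. Line 1 against line 2, 0 genes, gave 17, 23, 12 with only their groups and 80 without the number 3 libraries. Calls shared by the lines, 4 genes, numbered 252 with DESeq2, 292 with the likelihood ratio test, 8 with log2(TPM + 0.1), 2 at 0.01 and 748 without the number 3 libraries.

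The labels do not say that replicate numbers pair the samples, and not every pair passed a correlation of 0.1, with deviations of libraries that share a title number correlated at 0.101, 0.0350 and 0.326 for the 3 pairs of groups and those that share a description number at 0.101, -0.0350 and 0.326, so no pairing was used. With the title numbers as a replicate block, 337 genes were called for both lines, 20 for line 1, 3 for line 2 and 0 between the lines, and 3 of the 4 shared calls remained. With the description numbers as the block, the counts were 317 for both lines, 77 for line 1, 169 for line 2, 7 between the lines and 43 shared. The plastid set kept its call under both blocks, the RNA polymerase sum passed with the title block (edgeR adjusted p = 0.0413) and the end of NO09 with the description block (edgeR adjusted p = 0.0151).

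Leaving out 1 library in turn, which leaves a lone library assumed to vary like the other groups, gave 2 to 2848 calls for both lines, 2 to 3153 for line 1, 1 to 1549 for line 2, 0 to 12 between the lines and 1 to 1417 shared. The correlation of the lines ranged from 0.571 to 0.838, was 0.836 with a filter of 5 CPM, and was 0.375 and 0.0620 with separate WT libraries.

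The plastid set had medians from -0.75 to -0.46 without 1 library. It lost its call with an estimated correlation (median -0.59, camera adjusted p = 0.945) and for line 1 alone (-0.38, camera adjusted p = 0.149). Without the number 3 libraries the median was -0.57. With fry of limma, which tests the set against no change and not against other genes, it did not pass (fry adjusted p = 0.149). Photosystem II reads without psbA ranged from -0.89 to -0.67. The only change of sign among named genes was psaB, at -0.16 without line 1 replicate 2 (range without 1 library -0.16 to 0.36). Of the other alternatives for named genes, 302 kept sign and side of the threshold, 19 lost the call and 9 gained it. Of the 25 plastid genes and 10 mitochondrial genes tested, those under 1 CPM rest on few reads.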

Other observations

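Among the tests in this part, the check of the plastid set without each WT library was set before its result was seen, and the other tests and the scan of neighbouring IDs were chosen only after.

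Among genes at an unadjusted p below 0.05 in the knockout lines against WT, lower ones outnumbered higher ones at each level of abundance. The share was 71.7% in those under 20 CPM, 62.2% in those from 20 to 100 CPM and 70.0% in those over 100 CPM. These p-values take an error pooled over the groups, and the part that the WT spread has in this excess was not tested. Of the 50 most abundant transcripts, 11 were lower and 1 higher at that threshold, and the median log2 change of the 50 was -0.01. In line 2 against WT, the run of 15 consecutive tested IDs farthest from 0 lay in prefix NO10, with a median of -1.21 (largest of 100 shuffled orders 0.575 in size), and all 15 had fractional counts in at least 1 library, as reads divided among gene copies do. Across neighbouring IDs outside the NO06 run, log2 fold changes of the knockout lines against WT had a rank correlation of 0.154, and the difference between the WT libraries one of 0.162, both above every one of 1000 shuffled orders.

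The lower values of most plastid genes may have technical causes. A smaller amount of plastid RNA in the knockout libraries as the whole cause is disfavoured, because the 25 genes did not share 1 change (heterogeneity Q of 79.5 against a 5% limit of 36.4). One WT library alone is disfavoured as the source of the direction, since the median was -0.46 or lower without either, although the call was lost. A smaller carry-over of transcripts without a poly(A) tail cannot be told apart from a change in transcript level, since summed plastid reads without psbA minus mitochondrial reads gave a log2 change of -0.31 ± 0.18 (SE).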
